A study of Mus musculus with 9 samples.

How the data were processed

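The series holds 9 samples of the mouse kidney cell line SV40-MES-13, described by the submitters as mesangial. Poly(A)-selected RNA was sequenced in 5 libraries. These were 2 libraries of cells with an empty lentiviral vector (EV), 1 library of cells with the Drosha shRNA sh5 and 2 libraries of cells with the Drosha shRNA sh7. The library titles call the shRNA libraries knockouts, whereas the protocols describe shRNA knockdown, and knockdown is the word used here. The other 4 samples are small RNA libraries of control and Drosha knockdown cells, and they are not analysed here.

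The values deposited by the authors are TPM, transcript abundances scaled to a fixed sum, for 55357 Ensembl mouse genes, and each library sums to 1000000 TPM. For the mRNA libraries kallisto 0.48.0 is named in the submitters' processing notes. The genome build, the annotation release and the way transcripts were summed to genes are not given in the sources used here. For the small RNA libraries the same notes name Bowtie 1.3.1, SAMtools and limma 3.62.0. TPM keep no sequencing depth, so the number of reads per library is unknown and no counting error or detection floor was derived. An exact 0 can be a failed estimate, so such genes are given as listed at 0, without a fold. Genes that share sequence with pseudogenes share reads, and the way those reads were divided is not given.

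Gene symbols came from the deposited table. Of 22339 genes with no symbol there, 19991 were named from a mouse reference table (assembly GRCm38.p6), to which 52081 IDs matched. That table was also used for the order of neighbouring genes, and no coordinates were taken from it.

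Tests were run in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with a mean-variance trend) on log2(TPM + 1). The 12728 genes with a mean of at least 1 TPM over the 5 libraries were tested, and p-values were adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. All tests were two-sided. The pooled comparison set the 3 shRNA libraries against the 2 EV libraries in a model with 2 arms and 3 residual degrees of freedom. The comparisons of sh7 with EV, of sh5 with EV and of sh7 with sh5 came from a model with 3 groups and 2 residual degrees of freedom, in which the lone sh5 library was assumed to vary like the other groups. Nothing in the labels says that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

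The tests, the groups, 30 gene lists and the rule for the genes named in the text were set before the data were examined. Lists were tested with camera at a preset inter-gene correlation of 0.01, beside camera with an estimated correlation and fry. Camera compares a list with all other genes, so its direction is relative to them, whereas fry asks whether the members move one way on balance. Adjustment was over the 30 lists. Drosha, Dgcr8 and Gata3 were always named. Otherwise the rule took up to 15 genes per direction for the pooled comparison and up to 5 for each other comparison, by size of change, from genes past the threshold with a mean of at least 5 TPM and no overlap between the groups. Where fewer than 5 passed, the 5 genes with the smallest unadjusted p in that direction were taken and are given as not past the threshold. Predicted gene models and pseudogenes were left out of that rule. For each list the 3 members with the smallest unadjusted p in the pooled comparison were also eligible. Some genes that meet the rule are not reported here.

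The procedure was tested on simulated data with 200 genes changed among the 12728. In the pooled comparison 84% of the simulated changes of 1 log2 unit and 100% of those of 2 log2 units were recovered. For sh7 against EV the shares were 82% and 99%, for sh5 against EV 67% and 93%, and for sh7 against sh5 66% and 98%. Each run also gave 11 to 15 false calls. The noise was drawn independently for each gene and library from the fitted spread, without an outlying library. Only genes above about 5 TPM were changed, and in the pooled run both constructs changed alike. Recovery in the real data may therefore be lower, and few calls do not show that few genes changed.

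Alternatives tried were other pseudocounts (0.1 and 0.5), no filter or a filter at a mean of 5 TPM, median-of-ratios scaling, quantile normalization, TPM rescaled without mitochondrial genes and the 20 most abundant genes, eBayes without trend or with robust estimation, the replicate number as a block, the mean of both shRNA effects in the model with 3 groups, each library left out in turn, and a separate EV library for each construct in their correlation. The last of these, and the alternatives for list tests of each construct alone, for list medians and for Drosha in sh7, were chosen after seeing the data.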

Results

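Poly(A) RNA was profiled in SV40-MES-13 cells, a mouse kidney line, to ask what depends on Drosha, the nuclear RNase that cuts primary microRNA transcripts. The series title names the ribosome and the transcription factor Gata3 as parts of the question. Cells with an empty vector (EV, n = 2) were compared with cells expressing the Drosha shRNAs sh5 (n = 1) or sh7 (n = 2), in TPM. Between 20280 and 22045 genes lay above 0 TPM in each library. Across the 12728 tested genes the EV replicates correlated at r = 0.968 and 613 genes differed more than 2-fold between them, against r = 0.983 and 286 genes for the sh7 replicates. EV replicate 2 correlated with the sh5 library at r = 0.982 and with the sh7 libraries at r = 0.978, above its correlation with EV replicate 1. The small RNA libraries of the series were not analysed here.

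Drosha mRNA was at 60.0 and 56.4 TPM in the EV libraries, 36.0 TPM in the sh5 library and 8.39 and 14.9 TPM in the sh7 libraries. The mean was 58.2 ± 2.57 TPM in EV (SD, n = 2) and 11.7 ± 4.63 TPM in sh7 (SD, n = 2). The log2 difference was -2.27 (SE 0.266) for sh7, with an adjusted p of 0.109 over all genes and 0.00503 adjusted over the list alone, that list being 24 tested genes of microRNA biogenesis and silencing. For sh5 it was -0.68 (SE 0.326, adjusted p = 0.572), and for all knockdown libraries together -1.74 (SE 0.534, adjusted p = 0.908). The sh7 libraries lay -1.60 log2 units from the sh5 library (SE 0.326, adjusted p = 0.135 over all genes and 0.0195 adjusted over the list alone).

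**Figure D1:**
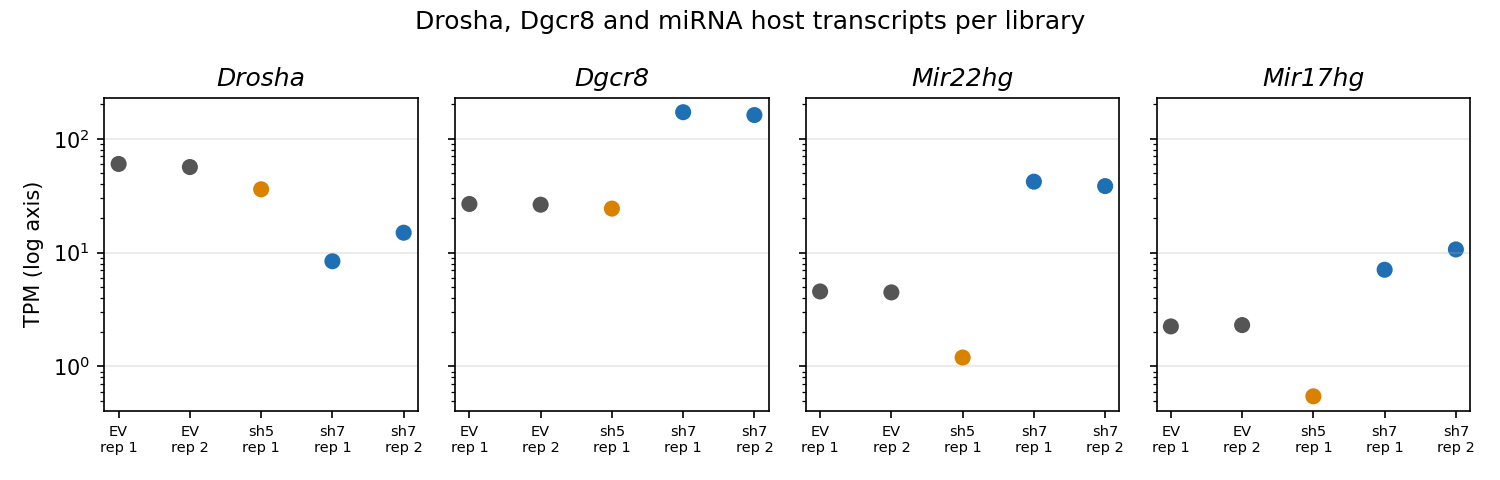
TPM on a log axis of Drosha, Dgcr8, Mir22hg and Mir17hg in each of the 5 libraries (EV grey, sh5 orange, sh7 blue; each point is 1 library). Drosha lies at 8.39 and 14.9 TPM in the sh7 libraries and at 36.0 TPM in the sh5 library, and Dgcr8 at 171 and 161 TPM in the sh7 libraries against 24.3 to 26.7 TPM in the other libraries.

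With both shRNAs pooled against EV, the genes with the smallest p on the higher side were the hairpin locus Mir6236, Rnf25, Zfp119b, Cyp4f13 and Hemk1. Rnf25 was at 38.3 and 40.5 TPM in EV and 52.8 to 65.4 TPM in the knockdown libraries. On the lower side were Insig1, a sterol-regulated inhibitor of cholesterol synthesis, the mitotic spindle gene Ckap2l, the histone H4 methyltransferase Kmt5a, the ubiquitin ligase Marchf7 and Rp2. Insig1 was at 147 and 130 TPM in EV and 93.6 to 101 TPM in the knockdown libraries, and Ckap2l at 82.8 and 74.1 TPM against 43.8 to 55.8 TPM. None of these 10 genes passed the threshold, with log2 differences of 0.49 (SE 0.0890) for Mir6236, -0.50 (SE 0.102) for Insig1 and -0.71 (SE 0.146) for Ckap2l, each at an adjusted p of 0.908. Gata3 was below the filter, at 0.0872 and 0.396 TPM in EV, 0.50 TPM in sh5 and 0.559 and 0.390 TPM in sh7. Without a filter its log2 difference was 0.27 (SE 0.138, adjusted p = 0.908).

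By limma, 3 genes passed the threshold in this comparison, named here after their values were seen because the rule leaves out pseudogenes and predicted models. The mitochondrial pseudogene Atp6-ps fell from 1094 and 1356 TPM in EV to 281 to 306 TPM, by 2.04 log2 units (SE 0.117, adjusted p = 0.0254). The predicted gene Gm47250 was at 7.86 and 8.15 TPM in EV and listed at 0 in the knockdown libraries, and AC144621.1 was listed at 0 in EV and at 6.55 to 8.13 TPM in knockdown (both adjusted p = 0.0369). All 3 can share reads with near-identical copies and are uncertain. At an unadjusted p under 0.05 there were 478 genes, 309 higher and 169 lower, where 636 are due by chance, and 1532 genes lay above and 917 below both EV libraries in every knockdown library, where chance gives 10% of the 12728 each way. These shares were 10.1% above and 9.48% below under median-of-ratios scaling, and 10.1% and 10.8% under quantile normalization. No gene passed without EV replicate 1, without EV replicate 2, or without either sh7 library (0 genes each, with 154 to 956 at an unadjusted p under 0.05), and without the sh5 library 3 genes passed, 0 of them shared.

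Among the fixed lists, type I interferon response genes were higher in the pooled knockdown, with 52 of 52 members above EV and a median log2 difference of 1.76. The antiviral factor Oas1b was at 0.562 and 19.1 TPM in EV, 17.0 TPM in sh5 and 49.95 and 40.2 TPM in sh7. The immunoproteasome gene Psmb8 was at 17.3 and 144 TPM in EV, 133 TPM in sh5 and 220 and 283 TPM in sh7. EV replicate 1 held the lowest value of 51 of the 52 members. NF-kB and inflammatory mediators (median 0.29), among them the chemokine Ccl2 at 550 and 1063 TPM in EV and 1326 to 1456 TPM in knockdown, and p53 target genes (median 0.16), among them the antiproliferative gene Btg2, rose against other genes. Cholesterol synthesis genes (median -0.19, 23 of 25 lower), G2 and M phase genes (-0.09, 41 of 53 lower), the unfolded protein response (-0.12), cytosolic ribosomal proteins (-0.05, 60 of 82 lower), cytosolic translation factors (-0.05) and mitochondrially encoded mRNAs (-0.54, 13 of 13 lower) fell against other genes. None of these 9 lists held with an estimated correlation (adjusted p = 0.810 with an estimated correlation for the ribosomal proteins and 0.723 for the other 8) or by fry (smallest FDR 0.808). Within the ribosomal proteins members went both ways: Rpl29 was at 40.3 and 37.5 TPM in EV and 28.0 to 34.0 TPM in knockdown, and Rpl12 at 102 and 182 TPM against 201 to 205 TPM.

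By camera these 9 of 30 lists were called, with adjusted p from 8.9e-17 for the interferon list to 0.0105 for the mitochondrially encoded mRNAs and 0.000894 for the cytosolic ribosomal proteins. Of their members 0 passed over all genes and 0 adjusted over the list alone. Without EV replicate 1, 7 calls were lost (adjusted p 0.112 to 0.574) and 3 lists were called in all, ribosomal proteins and translation factors (-0.07) among them. The medians then were 0.20 for interferon (adjusted p = 0.280), 0.07 for NF-kB, 0.07 for p53, -0.04 for cholesterol, -0.04 for the unfolded protein response, -0.15 for mitochondrially encoded mRNAs and 0.01, the other way, for G2 and M. Without EV replicate 2 they were 3.33 for interferon, 0.64 for NF-kB, 0.34 for p53, -0.34 for cholesterol, -0.20 for the unfolded protein response, -0.91 for mitochondrially encoded mRNAs, -0.20 for G2 and M and -0.02 for ribosomal proteins, with the ribosomal protein and translation factor calls lost (0.212 to 0.217). Without the sh5 library the mitochondrially encoded (turned to 0.26), G2 and M (-0.00672), p53 and NF-kB calls were lost (0.0594 to 0.892), and the medians were -0.14 for ribosomal proteins, -0.09 for translation factors, -0.20 for the unfolded protein response and -0.13 for cholesterol. Leaving out sh7 replicate 1 ended the ribosomal protein (-0.03) and unfolded protein response (-0.06) calls (0.0648 to 0.0681), with the mitochondrially encoded median at -0.81. Leaving out sh7 replicate 2 ended those for ribosomal proteins (turned to 0.01), translation factors (-0.00859), NF-kB and the unfolded protein response (-0.03; 0.0800 to 0.762), with -1.32 for mitochondrially encoded mRNAs and 0.29 for p53. Under quantile normalization the ribosomal protein, translation factor and mitochondrially encoded calls were lost (adjusted p 0.0763 to 0.0780).

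The other 21 lists were not called in the pooled comparison (adjusted p 0.0509 to 0.966). MicroRNA host transcripts had a median of 0.77 over 5 tested members (adjusted p = 0.115), miR-17 to 92 target genes 0.12, replication-dependent histones 0.54, the integrated stress response 0.10, glycolysis and hypoxia genes 0.10, S phase genes 0.06 and nuclear-encoded oxidative phosphorylation 0.04. In the integrated stress response list the transcription factor Ddit3 was at 12.6 and 35.2 TPM in EV and 43.5 to 58.7 TPM in knockdown. Medians below 0 were found for miR-29 target genes (-0.03), ribosome biogenesis factors (-0.02), collagens and basement membrane (-0.03), TGF-beta responsive genes (-0.01), angiogenic and vascular guidance factors (-0.06) and GATA transcription factors (-0.21, 4 tested). Median, mean and test differed in sign for microRNA biogenesis and silencing (median -0.02, mean 0.02), let-7 target genes (median -0.00145, mean 0.06) and mitochondrial ribosomal proteins (median 0.01, mean 0.02, camera lower).

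**Figure D2:**
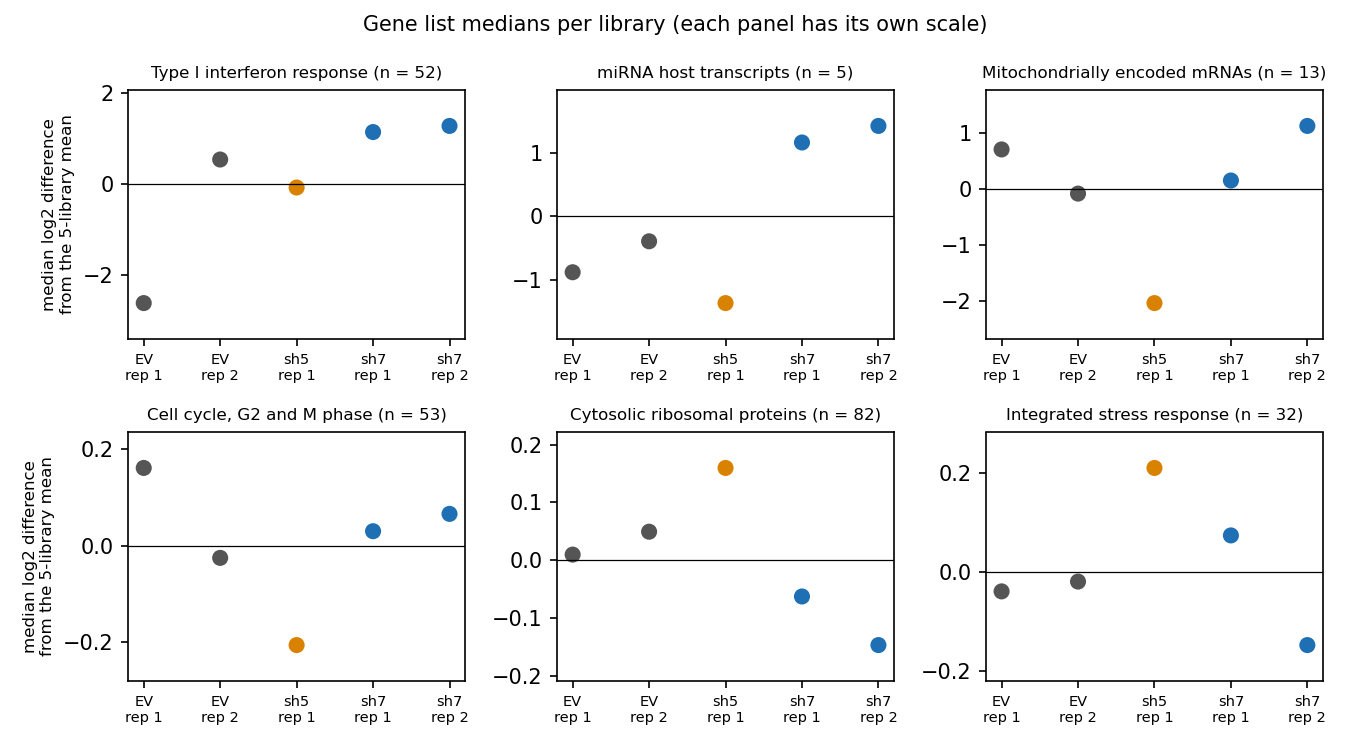
Median over list members of the log2 difference from the mean of the 5 libraries, for 6 gene lists, 1 point per library, with a separate scale in each panel (EV grey, sh5 orange, sh7 blue). For the interferon list EV replicate 1 lies at -2.63 and the other libraries between -0.08 and 1.28.

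In the sh7 libraries Dgcr8, which encodes the RNA-binding partner of Drosha, rose from 26.7 and 26.3 TPM in EV to 171 and 161 TPM, and the host transcript Mir22hg from 4.55 and 4.46 TPM to 42.0 and 38.4 TPM. The log2 differences were 2.60 (SE 0.0887, adjusted p = 0.0153) for Dgcr8 and 2.90 (SE 0.143, adjusted p = 0.0456) for Mir22hg. Other host transcripts were higher as well: Mir17hg at 7.06 and 10.6 TPM against 2.24 and 2.30 TPM and Mir100hg at 9.36 and 6.84 TPM against 1.36 and 3.79 TPM. Both passed limma adjusted over the list alone (adjusted p = 0.00312 and 0.0211). So did the hairpin locus Mir23a, 1 of the 5 tested members of the host transcript list. It was listed at 0 in EV and sh5 and at 11.5 and 8.17 TPM in sh7. Mir23a met the filter only through its sh7 values, so tests of that list that involve sh7 rest partly on this selection. Mir29a was listed at 0 in EV and at 11.3 and 21.1 TPM in sh7. Among genes below EV in both sh7 libraries that did not pass the threshold were the phosphatase inhibitor Ppp1r14b (511 and 489 TPM in EV, 266 and 261 TPM in sh7), Carnmt1, Bloc1s4 and Bzw2, with log2 differences from -0.92 (SE 0.0729, Ppp1r14b) to -1.57 (SE 0.142, Bloc1s4) and adjusted p from 0.0938 to 0.108.

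Dgcr8 and Mir22hg were the 2 genes that limma called for sh7, beside 1844 genes at an unadjusted p under 0.05 (1316 higher, 528 lower, 636 due by chance). In both sh7 libraries 35.8% of genes lay above and 14.3% below both EV libraries, against 16.7% each way by chance, and the median of all genes was 0.09. The imbalance of higher over lower genes followed the scaling. The shares were 24.2% above and 23.5% below under median-of-ratios scaling, and 21.3% and 25.3% under quantile normalization, where the median moved by -0.08 and -0.11. Under both, each share stayed above the 16.7% due by chance, so an excess of separated genes remained. Without EV replicate 1 or without either sh7 library 0 genes passed (744 to 1753 at an unadjusted p under 0.05), with Dgcr8 still at 2.56 to 2.64 and Mir22hg at 2.84 to 2.96 (adjusted p 0.114 to 0.525). More genes passed without EV replicate 2, Dgcr8 and Mir22hg among them, but EV replicate 1 was then the only control. A deviation of that library cannot be told there from an effect of sh7.

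Camera called 8 lists for sh7. Each had an adjusted p = 0.801 with an estimated correlation, and fry called the microRNA host transcripts alone (FDR 0.00221). MicroRNA host transcripts (median 1.57, adjusted p = 5e-05) and the interferon response (median 2.21, adjusted p = 9.03e-09) rose. Cytosolic ribosomal proteins fell, with 75 of 82 members lower and a median of -0.14 (adjusted p = 9.77e-18), as did translation factors (-0.09), mitochondrial ribosomal proteins (-0.06), ribosome biogenesis factors (-0.03), the unfolded protein response (-0.20) and cholesterol synthesis (-0.13). Adjusted over the list alone 17 memberships passed, against 2 over all genes. Of all 1844 genes at an unadjusted p under 0.05 by limma, 1316 were higher in sh7. Among the 17 memberships were 5 miR-17 to 92 targets, all higher, although camera did not call that list for sh7. These were Ankrd52, the histone methyltransferase Ezh1, the integrin Itga5, the NF-kB inhibitor Tnfaip3 and Zbtb4 (log2 0.56 to 0.85). The translation genes Eif3i (-0.45) and Eif4ebp1 (-0.59) and the sterol genes Ebp (-0.66) and Insig1 (-0.52) passed as well. Median, mean and test differed in sign for let-7 and miR-29 targets, oxidative phosphorylation, the integrated stress response, collagens, TGF-beta responsive genes and mesangial, podocyte and epithelial markers, none of them called. The host transcripts had a median of 0.61 over 15 members with no filter (adjusted p = 0.0213) and were too few to test at a mean of at least 5 TPM. The cholesterol call was lost without EV replicate 1 (adjusted p = 0.482), where its median turned to 0.07 (-0.29 without EV replicate 2, -0.20 without sh7 replicate 1 and -0.07 without sh7 replicate 2), the ribosome biogenesis call without EV replicate 2 (0.340), where its median turned to 0.01, and the mitochondrial ribosomal protein call without sh7 replicate 2 (0.0932), where its median was -0.02 (-0.04 without EV replicate 1). Without sh7 replicate 2 the ribosome biogenesis median turned to 0.00105 with the call kept (adjusted p = 0.0417), and it was -0.07 without EV replicate 1 and -0.06 without sh7 replicate 1. The number of called lists was 13 without EV replicate 2, 13 without sh7 replicate 1 and 14 without sh7 replicate 2. The interferon median was 0.65 without EV replicate 1, where 51 of 52 members were lowest, and 3.74 without EV replicate 2. Without EV replicate 1 the list was still called at the preset correlation. An estimated correlation cannot decide there, as it rests on 1 residual degree of freedom. The medians of ribosomal proteins and translation factors were -0.09 and -0.05 without sh7 replicate 2. Under quantile normalization the ribosomal protein median was -0.08, with the call kept.

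In the sh5 library the nuclear import receptor gene Kpna2 was at 2.01 TPM, against 45.9 and 31.1 TPM in EV. The splicing-associated Ppig was at 22.6 TPM against 71.9 and 62.3 TPM, the condensin gene Smc4 at 63.3 TPM against 153 and 139 TPM and the kinase Slk at 36.2 TPM against 69.3 and 69.0 TPM, and Mir186 was listed at 0 in sh5. On the higher side were ribosomal RNA Rn18s, Rdm1, Mir6236, Ttc33 and Cfap157, of which Rdm1 was at 20.2 TPM against 10.5 and 11.1 TPM. None passed the threshold, with log2 differences of -3.69 (SE 0.266, adjusted p = 0.280) for Kpna2, -1.19 (SE 0.113, adjusted p = 0.342) for Smc4 and 0.84 (SE 0.155, adjusted p = 0.391) for Rdm1. Mir22hg at 1.20 TPM and Mir17hg at 0.545 TPM were below both EV libraries, and Dgcr8 was at 24.3 TPM (log2 -0.12, SE 0.109, adjusted p = 0.719).

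By limma 0 genes passed for sh5, beside 1216 at an unadjusted p under 0.05 (203 higher, 1013 lower, 636 due by chance). Without EV replicate 2, 59 genes passed, 55 of them higher. The sh5 library was above both EV libraries for 26.9% of genes and below them for 43.7%, against 33.3% each way by chance. Under median-of-ratios scaling the shares were 36.2% and 35.1%, and under quantile normalization 36.8% and 33.0%, with the median of all genes moved from -0.05 by 0.06 and 0.07.

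Camera called 15 lists for sh5. None of the 15 held with an estimated correlation (adjusted p = 0.695 with an estimated correlation for the interferon and NF-kB lists and 0.624 for the other 13) or by fry (smallest FDR 0.126). Mitochondrially encoded mRNAs fell by 2.42 log2 units in the median (adjusted p = 1.52e-09). Of the 13 members, 11 passed adjusted over the list alone and 0 over all genes, among them mt-Nd4 (-2.94, SE 0.473) and mt-Co1 (-2.16, SE 0.386). The share of TPM in these mRNAs was 0.396% in sh5, 1.16% and 0.860% in EV and 0.751% and 1.42% in sh7. G2 and M phase genes fell (median -0.21, 45 of 53 lower), and 8 of them passed adjusted over the list alone, including the proliferation marker Mki67 (-1.42), the centromere proteins Cenpe (-1.46) and Cenpf (-1.22), and Smc4. Cholesterol synthesis (-0.30), microRNA biogenesis (-0.21), host transcripts (-0.52), miR-29 targets (-0.34) and podocyte markers (-0.34) also fell. Cytosolic ribosomal proteins rose (0.13, 71 of 82 higher), with mitochondrial ribosomal proteins (0.12), oxidative phosphorylation (0.05), histones (0.36), p53 targets (0.33), the integrated stress response (0.25, 30 of 32 higher), NF-kB mediators (0.22) and the interferon response (0.96).

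Adjusted over the list alone 24 memberships passed, against 0 over all genes. Without EV replicate 1 the interferon median turned to -0.59, and without EV replicate 2 it was 2.67. Each sets 1 sh5 library against 1 EV library, so these differences have no replicate check, although camera at the preset correlation then called the list lower and higher. Leaving out EV replicate 1 ended the calls for miR-29 targets, histones, NF-kB mediators and podocyte markers (adjusted p 0.0531 to 0.713), with the NF-kB median at -0.08. Without EV replicate 2 the calls for microRNA biogenesis, host transcripts, oxidative phosphorylation and podocyte markers ended (0.0564 to 0.168), and the NF-kB call ended without sh7 replicate 1 (0.170) or 2 (0.168). The medians without EV replicate 1 were -0.12 for G2 and M phase genes, -0.15 for cholesterol synthesis, 0.16 for p53 targets, -1.04 for host transcripts, -0.16 for miR-29 targets, 0.23 for histones and 0.09 for oxidative phosphorylation. Without EV replicate 2 they were -0.36 for G2 and M phase genes, 0.49 for p53 targets and -0.57 for miR-29 targets. Under quantile normalization the ribosomal protein, oxidative phosphorylation and NF-kB calls were lost (0.0513 to 0.117), with the ribosomal protein median at 0.03 and that of all genes at 0.02. With no filter those for host transcripts, miR-29 targets, NF-kB mediators and podocyte markers were lost (0.0905 to 0.323), at a mean of at least 5 TPM that for histones (0.0792), under median-of-ratios scaling that for NF-kB mediators (0.0816) and with TPM rescaled that for podocyte markers (0.0549). Host transcripts were too few to test at a mean of at least 5 TPM. Median, mean and test differed in sign for let-7 targets, ribosome biogenesis factors, translation factors, S phase genes, glycolysis genes and endothelial markers, none of them called.

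The constructs differed directly in Dgcr8, which was 2.72 log2 units higher in sh7 than in sh5 (SE 0.109), and in Mir22hg, which was 4.23 units higher (SE 0.175, both adjusted p = 0.0198). The genes Zc3h7a (58.5 and 65.1 TPM in sh7, 19.3 TPM in sh5) and Kpna2 (27.4 and 32.1 TPM against 2.01 TPM) were higher in sh7 without passing the threshold, as was Mir186. Ppp1r14b, Slc35c2, the spliceosome assembly gene Smn1 and Bloc1s4 were lower, with log2 differences of -1.05 to -1.57 and adjusted p of 0.111 to 0.115. By limma these 2 genes passed, beside 2632 at an unadjusted p under 0.05 (2179 higher, 453 lower), and 58.5% of genes were higher and 23.9% lower in both sh7 libraries than in sh5, against 33.3% each way by chance. Under median-of-ratios scaling the shares were 41.7% and 39.6%, and under quantile normalization 35.9% and 43.7%. Without either EV library 4 genes passed, and without either sh7 library 0 passed (1043 and 1507 at an unadjusted p under 0.05), with Dgcr8 at 2.68 and 2.76 and Mir22hg at 4.16 and 4.29 (adjusted p 0.417 and 0.577).

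The median of all genes between sh7 and sh5 was 0.16, and it moved by -0.15 under median-of-ratios scaling and by -0.19 under quantile normalization. Camera called 12 lists. Their adjusted p with an estimated correlation was 0.671 to 0.718, and fry called the host transcripts alone (FDR 0.00172). Host transcripts (median 2.65), mitochondrially encoded mRNAs (2.64), microRNA biogenesis (0.42) and miR-17 to 92 targets (0.42) were higher in sh7. Cytosolic ribosomal proteins (-0.24, 80 of 82 lower), mitochondrial ribosomal proteins (-0.17), ribosome biogenesis factors (-0.07), translation factors (-0.10), oxidative phosphorylation (-0.04), p53 targets (-0.04), the integrated stress response (-0.27) and the unfolded protein response (-0.20) were lower relative to other genes. Adjusted over the list alone 52 memberships passed, against 2 over all genes, including the terminal uridylyltransferases Tut4 (1.08) and Tut7 (0.72) and 8 miR-17 to 92 targets, of which the retinoblastoma family members Rbl1 and Rbl2 were higher by 0.67 and 0.91. The biogenesis and miR-17 to 92 calls were lost without sh7 replicate 2 (adjusted p 0.101 to 0.107), where the medians of translation factors, the integrated stress response and ribosome biogenesis factors were -0.04, -0.14 and -0.01. The p53 median was -0.11 without sh7 replicate 1, and the ribosomal protein median -0.11 under quantile normalization. The oxidative phosphorylation call was lost under quantile normalization (0.224) and the p53 call with no filter (0.0739), and host transcripts were too few to test at a mean of at least 5 TPM. Median, mean and test differed in sign for let-7 targets, NF-kB mediators, angiogenic factors and mesangial, epithelial and macrophage markers, none of them called.

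Across genes, which are not independent replicates, the sh5 and sh7 differences from EV correlated at r = 0.302 (rho = 0.211), below the mean of 0.408 (0.346 to 0.446) for 100 simulated pairs of unchanged groups set against the same EV libraries. Their covariance was 0.0538 against a simulated mean of 0.0326 (0.0265 to 0.0374), a difference of 0.0212. The covariance thus lay above every simulated value, whereas r lay below every simulated value. The EV replicates differed more than the sh7 replicates (613 against 286 genes over 2-fold), and a larger spread of shared controls by itself raises the covariance. The covariance above the simulated range therefore does not show an effect shared by the constructs. The same sign was seen for 52.7% of genes, against 63.4% simulated. At an unadjusted p under 0.05, 65 genes were higher with both constructs where independent lists give 20.99, 48 were lower with both where they give 42.0, and 87 went opposite ways. With 1 EV library for each construct and none shared, a split chosen after the data were seen, the correlation was -0.0369 and -0.129, so part or all of the agreement may come from the shared controls. Without EV replicate 2 the correlation was 0.632.

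**Figure D3:**
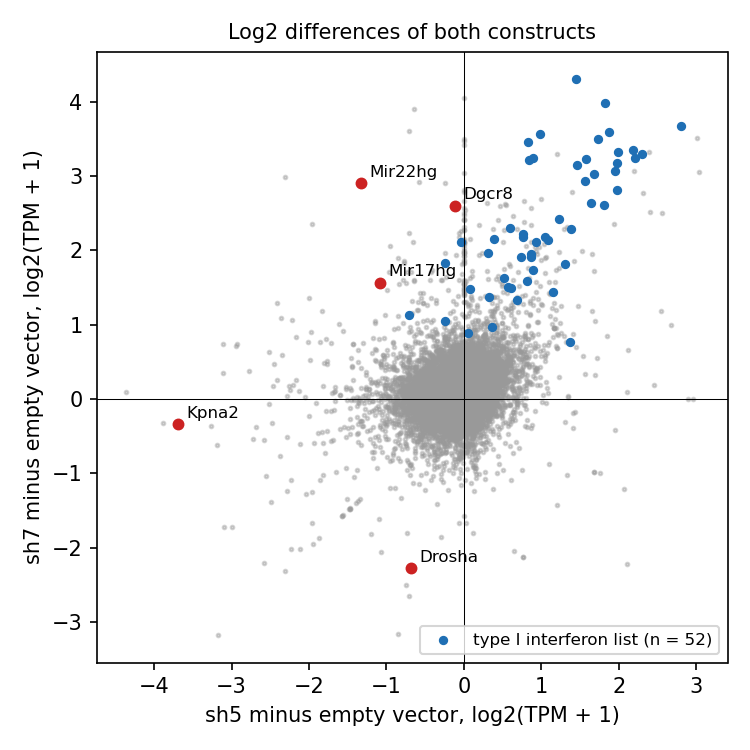
Log2 difference from EV of each tested gene in sh5 (1 library) and sh7 (2 libraries), with interferon response genes in blue and 5 named genes in red. Dgcr8 lies at 2.60 for sh7 and -0.12 for sh5, and the correlation across genes is 0.302.

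In every library epithelial genes were more abundant than mesangial genes, with list medians of 2.50 to 5.41 TPM and 0.125 to 0.231 TPM. Of the kidney tubule and epithelial markers, 19 of 30 had a mean of at least 1 TPM, among them the keratin Krt18, kidney cadherin Cdh16, Epcam and the kidney transcription factor Pax8. Of 40 mesangial and pericyte markers, 11 had a mean of at least 1 TPM and 5 of at least 10 TPM, while 27 were below 1 TPM in every library, including the PDGF receptor gene Pdgfrb, Acta2 and the integrin Itga8. Vim was at 848 and 794 TPM in EV and 498 to 653 TPM in knockdown. Podocyte markers had 11 of 28, endothelial markers 4 of 26 and macrophage and leukocyte markers 6 of 26 members at a mean of at least 1 TPM. The median log2 difference of the pooled knockdown was 0.09 for epithelial, -0.09 for mesangial, -0.08 for podocyte, -0.24 for endothelial and 0.22 for macrophage markers, and none of these lists was called (adjusted p 0.0509 to 0.555).

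**Figure D4:**
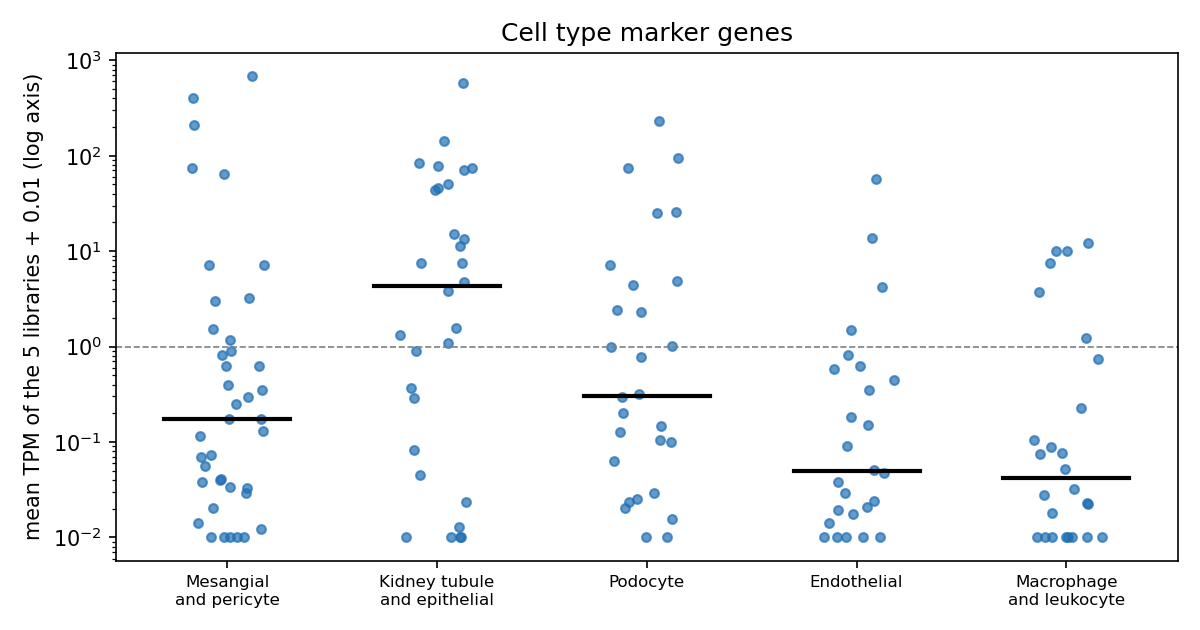
Mean over the 5 libraries of TPM + 0.01, on a log axis, for each marker gene of 5 cell type lists (1 point per gene, bar at the list median, dashed line at 1 TPM). The median is 4.28 TPM for epithelial and 0.164 TPM for mesangial and pericyte markers.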

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

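The tests of explanations here were chosen only after the result was seen.

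The direct test between the constructs singled out 2 genes, Dgcr8 (2.72 log2 units higher in sh7 than in sh5) and Mir22hg (4.23 higher), and 12 lists. The list medians, sh7 minus sh5, were 2.65 for microRNA host transcripts, 2.64 for mitochondrially encoded mRNAs, 0.42 for microRNA biogenesis and silencing, 0.42 for miR-17 to 92 targets, -0.24 for cytosolic ribosomal proteins, -0.17 for mitochondrial ribosomal proteins, -0.0690 for ribosome biogenesis factors, -0.10 for translation factors, -0.0395 for oxidative phosphorylation, -0.0436 for p53 targets, -0.27 for the integrated stress response and -0.20 for the unfolded protein response. The sh5 side of each rests on 1 library, and no list held with an estimated correlation (smallest adjusted p = 0.671).

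Cytosolic ribosomal protein genes were higher in the sh5 library and lower in the sh7 libraries than in EV, but under quantile normalization the sh5 median was 0.0349 (adjusted p = 0.108) against 0.130 as deposited, and the median of sh7 minus sh5 was -0.109. A different share of TPM in a few abundant genes would move other genes alike, so by itself it gives no gap from them. As deposited, the list lay -0.396 from the median of all genes between sh7 and sh5 (81 of 82 members below it, quartiles -0.474 and -0.346). Camera had already called the list lower than other genes, so this value restates that call and is no separate test. Under quantile normalization the median of all genes was -0.0324, nearer to the -0.109 of the list, and the call of the list was kept. That method gives every library the same distribution of values. The list lies high in it, with medians of 1517 to 1863 TPM per library. The smaller gap therefore cannot tell a real shift of these genes from a spurious one. A shift of short mRNAs in general may account for the pattern, as the oxidative phosphorylation list lay -0.197 and the mitochondrial ribosomal protein list -0.329 from the median of all genes. Camera had already called both lists lower in that comparison, so they are no independent check. Gene lengths were not available for a direct check. An effect of Drosha level or of a construct on ribosomal protein mRNA stays open and was not tested apart from that shift.

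Interferon response genes were higher in the pooled knockdown than in EV, and EV replicate 1 was far below the other libraries. Without that library the median fell from 1.76 to 0.197 for the pooled knockdown and from 0.956 to -0.591 for sh5, so those higher values depended on the low levels already seen in that library. For sh7 the median was 0.646 without it, against 2.21 with it. Between sh7 and sh5, a difference in which the EV values cancel, the list median was 1.18, resting on 1 sh5 library. Camera did not call the list there in the main fit. It called the list higher in sh7 with either EV library left out, the median being unchanged, and under median-of-ratios scaling or quantile normalization. The EV libraries enter that test only through the spread. With 1 remaining EV library, whether sh7 or sh5 differs stays open, as the control then has no replicate. The sh7 call was kept at the preset correlation and lost with an estimated one. That estimate rests on 1 residual degree of freedom, from the sh7 libraries, so its loss decides nothing. The lower values in sh5, 1 library against 1, have no replicate check. Whether the low values of EV replicate 1 or the higher ones of the other libraries are usual for these cells was not tested.

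MicroRNA host transcripts and most tested hairpin loci were higher in sh7 and not in sh5. Of 43 tested hairpin loci 38 were higher in sh7 and 6 in sh5, but 18 were listed at 0 in every library but sh7. The most abundant, Mir6236, was higher with both constructs, at 4690 and 4780 TPM in EV, 6689 TPM in sh5 and 6704 and 6531 TPM in sh7. More intronic RNA in sh7 stays open: among loci with an EV mean of at least 1 TPM, small nucleolar RNAs, also mostly intronic, had a median of 0.120 (23 of 42 higher, quartiles -0.379 and 0.765) against 0.493 for hairpin loci (15 of 20 higher, quartiles 0.00399 and 0.802). A general rise of nuclear RNA stays open too, with a median of 0.359 (11 of 14 higher) for other nuclear noncoding RNAs. Less cleavage by Drosha, a role known for it on primary transcripts and on Dgcr8 mRNA, is a candidate explanation for sh7, while in sh5, where Drosha was at 36.0 TPM, the host transcripts had a median of -0.524. A threshold of Drosha level and a property of the single sh5 library cannot be told apart with 1 library.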

How the results depend on the processing

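The alternatives for list tests of each construct alone, for list medians and for Drosha in sh7, and the split of the EV libraries, were chosen only after the results were seen. The Drosha differences kept their direction and their side of the threshold under every alternative run. Of the alternatives for named genes, 1881 kept side and direction, 16 passed newly, 22 no longer passed and 4 reversed. List medians were followed only for lists called in the main fit, none of which could pass newly. Of their alternatives, 575 kept call and direction, 44 lost the call and 8 reversed. Other lists gained calls under some alternatives, up to 8 of them in the pooled comparison, without sh7 replicate 2. Depth is unknown in TPM, so its effect on low genes could not be judged. Unless fewer genes or libraries explain a change, the cause was not tested.

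For the pooled knockdown the 3 called genes became 0 with no filter (1007 at an unadjusted p under 0.05), 1 at a mean of at least 5 TPM and 0 as the mean of both constructs in the model with 3 groups, and leaving out 1 library gave 0 to 3. For sh7 the 2 calls became 1 with a pseudocount of 0.1 or 0.5, 0 with no filter (3059 at an unadjusted p under 0.05), 4 at a mean of at least 5 TPM, 1 under median-of-ratios scaling, 1 under quantile normalization, 4 with TPM rescaled, 19 without the trend and 7 with robust estimation, and leaving out 1 library gave 0 to 281 (281 without EV replicate 2). The 4 called after rescaling were 3 higher and 1 lower, against 2 higher and 0 lower. For sh7 and for sh5, the counts without EV replicate 2 have EV replicate 1 as the only control. They cannot be told from a deviation of that library. For sh5 the count of 0 became 180 with no filter (175 higher), and leaving out 1 library gave 0 to 59 (59 without EV replicate 2). Between sh7 and sh5 the 2 calls became 251 with no filter (42 higher, 209 lower), 0 without the trend (2433 at an unadjusted p under 0.05) and 4 with robust estimation, and leaving out 1 library gave 0 to 4.

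The replicate number as a block gave 0 called genes for the pooled knockdown, 0 for sh7, 0 for sh5 and 0 between the constructs by limma, beside 583, 1594, 893 and 1859 at an unadjusted p under 0.05. The deviations of EV and sh7 replicate 1 from their group means correlated at r = -0.0158 across genes. With 2 libraries in each of these groups, that value cannot show whether libraries of the same number share a culture or batch. With the block the sh5 call for host transcripts was lost (adjusted p = 0.0538).

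Called lists numbered 9 for the pooled knockdown (0 with an estimated correlation, 0 by fry, 3 to 13 with 1 library left out), 8 for sh7 (0, 1 and 7 to 14), 15 for sh5 (0, 0 and 13 to 16) and 12 between the constructs (0, 1 and 10 to 15). With 1 library left out, the correlation of sh5 with sh7 differences ranged from 0.204 to 0.632 (0.632 without EV replicate 2). With EV replicate 1 for sh5 and EV replicate 2 for sh7 it reversed to -0.0369, and the other way round to -0.129. The other reversed values arose with 1 library left out, among the results recomputed. In the pooled comparison the ribosomal protein median ranged from -0.14 to 0.0142 (above 0 without sh7 replicate 2), the G2 and M median from -0.20 to 0.00868 (above 0 without EV replicate 1), the mitochondrially encoded median from -1.32 to 0.26, mt-Nd2 from -1.37 to 0.18 and Trps1 from -0.48 to 0.11 (all 3 above 0 without sh5), and Ramp2 from -0.98 to 0.00991 and Ecscr from -0.34 to 0.00607 (both above 0 without EV replicate 1). For sh7 the cholesterol median ranged from -0.29 to 0.0720 (above 0 without EV replicate 1) and the ribosome biogenesis median from -0.0750 to 0.0111 (0.0111 without EV replicate 2 and 0.00105 without sh7 replicate 2). The interferon median of sh5 ranged from -0.59 without EV replicate 1 to 2.67 without EV replicate 2, and its NF-kB median from -0.0838 without EV replicate 1 to 0.30.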

Other observations

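The test of neighbouring genes was set before its result was seen; those of mixed cells and of immediate-early genes were chosen only after the result was seen.

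More microRNA hairpin loci were above 0 TPM in the sh7 libraries, 70 and 87 of 1187, than in EV (36 and 43) or sh5 (23). Small nucleolar RNA loci above 0 numbered 45 and 42 of 146 in EV, 29 in sh5 and 45 and 46 in sh7. The host gene Dleu2 was at 18.6 and 22.1 TPM in sh7 against 4.71 and 6.36 TPM in EV and 2.89 TPM in sh5. The paraspeckle RNA Neat1 was at 112 and 78.6 TPM in sh7, 8.29 and 24.1 TPM in EV and 17.7 TPM in sh5.

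In sh7, 37 genes lay below a log2 difference of -0.8 at an unadjusted p under 0.01, Drosha among them. The count takes only genes with a mean of at least 5 TPM and both sh7 libraries below both EV libraries. Predicted gene models and pseudogenes were left out of these 37 genes. They included the G protein subunit gene Gnas (792 and 736 TPM in EV, 404 and 437 TPM in sh7), Cap1, Ddx1, Smn1 and the calcium-binding S100a16 (83.0 and 91.5 TPM against 33.4 and 40.1 TPM). Loss of a chromosome segment was tested on their 346 nearest tested neighbours in the reference order (GRCm38.p6). The median of the neighbours lay 0.000938 from that of all genes, within the -0.0535 to 0.0518 of 1000 random sets. A loss covering most of the 37 genes is therefore argued against. A loss covering only a few of them would hardly move that median and stays open. A search of the 3' untranslated regions of the 37 genes for the shRNA seed was not possible here.

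Epithelial genes were high and most mesangial genes near 0 TPM in cells described as mesangial. Epithelial cells mixed into a mesangial culture stay open: the highest library median of the mesangial and pericyte markers was 0.231 TPM, but 11 of 40 had a mean of at least 1 TPM and 5 of at least 10 TPM, and the levels usual for this line were not available. Krt18 was at 454 to 673 TPM and Cdh16 at 126 to 154 TPM over the 5 libraries. The identity of the cells was not tested further.

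Fos was at 5.28 TPM in EV replicate 1 and 0.818 to 2.30 TPM in the other libraries. An acute serum or handling response in that library was tested on 27 immediate-early genes, Fos among them, which had a median difference of 0.0995 log2 units from the other libraries (percentile 93.4 among random lists of like mean level) and of which 18 lay above the mean of the other libraries and 10 were highest there, against 5.4 by chance. Such a response therefore stays open.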
